A study of Mus musculus with 2 samples.

How the data were processed

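Neural stem cells from CD-1 mouse embryos at embryonic day 12 were cultured for 5 days and infected with control or H3.3 knockdown lentivirus, per the labels' protocols. From 2 µg of total RNA, polyadenylated RNA was enriched with oligo(dT), fragmented and reverse transcribed with random primers, and the libraries were sequenced on an Illumina HiSeq instrument, per the labels' protocols and the series' design text. Enrichment by oligo(dT) captures most replication-dependent histone transcripts poorly. The knockdown sequence and its target among the H3.3 genes are not given in the sources used here. The submitters' processing notes name TopHat2 2.0.12, Bowtie 1.0.1 and HTSeq 0.6.0. Their settings, the genome build and whether counting used strand are not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart, and genes with near-identical copies are uncertain.

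The values came from 1 deposited table with a column per library. Its counts are whole numbers of reads per gene as deposited, not normalized, per the file headers and from the values. Its normalized columns are in CPM, since the authors divided each count by 1 constant per library. Its fold change is the ratio of those CPM values, and its log2 fold change is the authors' log2 of that ratio. For 69 genes with no count in the control these differ by more than 0.01, because the authors put 0.5 of a count in place of 0 for the log2 value and 0.0287 of a count for the ratio. The fold change of Flt1 is 735 in the authors' deposited table, with a log2 fold change of 5.40. The authors' p-value and adjusted p-value come from a test that is not named in the sources used here. Per the series' design text, a gene counted as differential at a p-value under 0.05 and a log2 fold change over 1 in size, which 1257 genes meet in the authors' deposited table. The 1081 genes it marks are those that meet this with the adjusted p-value. In 5928 rows of the authors' deposited table the adjusted p-value is smaller than the p-value, which an adjustment for many tests does not usually give. These deposited p-values were used only to count the marked genes.

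The table lists 18510 genes, each with at least 2 counts over both libraries, and 1 further row is not analysed here. Symbols were found for 18423 of these Ensembl IDs (99.5%). The gene positions are those of the deposited table. Of these, 78.3% equal the positions in the GENCODE vM21 annotation of GRCm38, and 89.6% share at least 1 end with it. Transcript length, GC content and genomic length were taken from that annotation.

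Counts were divided by the total over all listed genes. The log2 ratio of knockdown over control was computed with 0.5 count added to each library. Its interval is the exact conditional (Clopper-Pearson) interval of the 2 counts at 95% and was computed without added counts. The intervals cover at most counting error and leave out the spread between cultures. Because PCR reads without molecular identifiers are not independent molecules, they may be too narrow even for counting error. With 1 library per group no model of the condition can be tested, so genes were described by a size rule. It asks for a mean of at least 1 CPM, a 2-fold ratio and a counting interval that excludes 1. A gene that met it is said to have risen or fallen, or to be higher or lower by the rule. The size rule, 35 gene lists, the named genes and most alternatives were fixed before the data were examined. Each list was described by the median log2 ratio of its tested members and that median's percentile among 10000 random lists of the same size, drawn from tested genes in the same 20 bins of mean expression. A list with at least 5 tested members was called outside the random range below percentile 2.5 or above 97.5. The random lists hold genes drawn at random within bins, whereas members of a fixed list may vary together. A percentile therefore describes the 2 libraries and is not a p-value.

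The named genes are H3f3a and H3f3b, the 12 higher and 12 lower genes whose interval lies farthest from 1 (predicted gene names left out), for each list up to 4 members past the rule or otherwise its 2 most abundant members, and Gli1, Ptch1, Kat8, Tubb3, Nes, Sox2, Gfap, Olig2, Mki67 and Cdkn1a. The further genes Hira, Daxx, Atrx, Ubn1, Ubn2, Cabin1, Syt1, Sst, Mog, Mdm2 and H19 were named in the report after their values were seen. Some genes that the rule selects are not reported here. The lists overlap, and 12 of their 546 tested genes count in more than 1 of them, among them Sp8, Mfng, Notch1 and Cdkn1a.

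The procedure was tested on simulated counts of the 18510 genes with no spread other than counting error. The rule recovered 2% of 50 genes changed 1.5-fold, 38% of 50 changed 2-fold, 98% of 50 changed 3-fold and 100% of 50 changed 4-fold. It called 57 of 18310 unchanged genes, none of them with a mean of at least 10 CPM. The 18310 include genes under the minimum of 1 CPM, which the rule cannot call. The intervals covered the true ratio in 95.6% of genes. Spread between cultures is not part of this test.

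The alternatives were TMM factors from edgeR 4.0.16 and size factors from DESeq2 1.42.0 (both used for scaling only), totals without the 20 most abundant genes, no filter or a minimum of 10 CPM, a fold threshold of 1.5 or 3, no interval, 5 counts added, the mean in place of the median and the authors' deposited log2 fold changes. A correction of the log2 ratios for transcript length, GC content and genomic length, and totals without mitochondrial genes, were added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3, were used.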

Results

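RNA was sequenced from neural stem cells of CD-1 mouse embryos at embryonic day 12, cultured for 5 days and infected with a lentivirus that carried either a control or an H3.3 knockdown plasmid. H3.3 is the histone H3 variant that can be placed into chromatin outside of DNA replication, and in the mouse the same protein is made from H3f3a and H3f3b. The comparison asks how the transcriptome of these cells differs after knockdown of H3.3. Each group held 1 library, so no difference below has a replicate check, and no p-value for the condition was computed. The control library held 9184779 counts over genes and the knockdown library 8702855, with medians of 285 and 258 counts per tested gene. A count of 0 allowed a level of up to 0.327 CPM (the count scaled to the library's total) in the control and 0.345 CPM in the knockdown library, taking 3 counts as the limit. All intervals are 95% intervals of the 2 counts and cover counting error only. Log2 ratios are knockdown over control throughout.

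Both H3.3 genes had lower counts in the knockdown library, and neither reached a 2-fold difference. H3f3b (ENSMUSG00000016559, chromosome 11 from 116021912 to 116027962, minus strand) held 821 CPM in the control and 447 CPM in the knockdown library, a level of 0.544 of the control (interval 0.523 to 0.566). H3f3a (ENSMUSG00000060743, chromosome 1 from 180800832 to 180813943, minus strand) went from 209 to 135 CPM, or 0.646 of the control (0.601 to 0.695). The log2 ratios were -0.88 and -0.63, and the median of the pair lay at percentile 0.66 of matched random pairs. The direction was that of the labels.

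Of 13989 genes with a mean of at least 1 CPM, 535 were higher and 355 lower in the knockdown library by the size rule, which asks for a 2-fold ratio and a counting interval that excludes 1. The median log2 ratio of all tested genes was -0.03, and 73.3% of them lay within 0.5 of 0. Among the 12 higher genes with intervals farthest from 1 were Etv4, a transcription factor induced by FGF signalling, and Dusp5, a phosphatase of ERK. Etv4 rose from 40 to 209 counts (5.51-fold, 3.92 to 7.94) and Dusp5 from 12 to 68 counts (5.98-fold, 3.21 to 12.1). The same group held Slc17a7, which loads glutamate into synaptic vesicles (3.64-fold, 3.11 to 4.28), the dopamine signalling protein Ppp1r1b (4.48-fold, 3.27 to 6.25) and Hmgcll1 (6.12-fold, 4.36 to 8.79). Flt1, a VEGF receptor, had no count in the control and 20 in the knockdown library, at least 7.04-fold higher against the limit of 3 counts with the 20 taken as exact, and the counting interval starts at 5.21-fold. The other members had few control counts, with 2 for Prrg4 and Epcam, 4 for Ttr and Apod, 7 for Car12 and 8 for Otof, against 36, 25, 38, 36, 54 and 61 in the knockdown library. At the lower end, Enpp6 went from 71 counts to 1, which is 0.0149 of the control level (0.000371 to 0.0855). The lactate transporter Slc16a3 fell to 0.0731 of the control (0.0287 to 0.156), Nkx2-3 to 0.0935 (0.0364 to 0.202), S100b to 0.109 (0.0421 to 0.236), Bmp4 to 0.135 (0.0672 to 0.247) and Gdf10 to 0.141 (0.0826 to 0.229). Vax1, Ptx3, Myrf, Cdca7, Bcas1 and Dlx2 completed the list, at 0.165, 0.173, 0.181, 0.220, 0.230 and 0.234 of the control level.

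**Figure D1:**
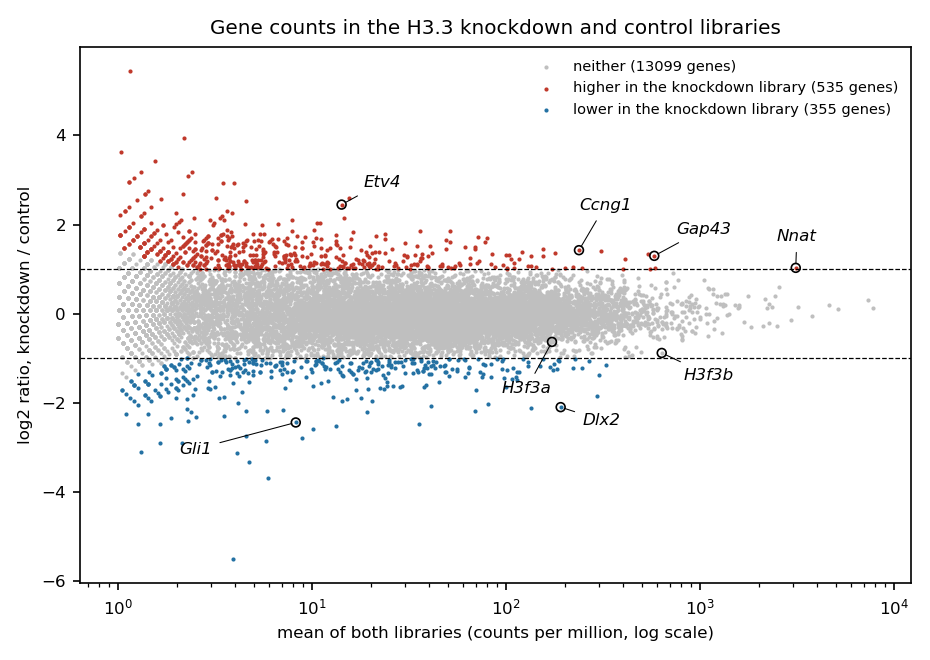
Log2 ratio of knockdown over control (vertical axis) against the mean of both libraries in CPM (horizontal axis, log scale) for each of 13989 tested genes, 1 library per group. Red points are the 535 genes higher and blue points the 355 genes lower by the size rule, dashed lines mark a 2-fold ratio, and H3f3a and H3f3b lie between the lines at -0.63 and -0.88.

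Genes of DNA replication were lower as a group. Of 28 tested members of the G1/S and DNA replication list 17 fell and none rose, with a median log2 ratio of -1.14, below all 10000 matched random lists. Cdc6, which loads the replicative helicase, fell to 0.274 of the control level (0.195 to 0.378), the helicase partner Cdc45 to 0.306 (0.231 to 0.402), Mcm10 to 0.327 (0.260 to 0.408), and the ribonucleotide reductase subunit Rrm2 from 1536 to 516 counts. Mitotic genes followed with smaller differences. All 30 members of the G2/M list had log2 ratios below 0, with a median of -0.76, again below all random lists, but only 3 passed the size rule, namely the regulator Foxm1 (0.429 of the control, 0.377 to 0.488), the kinase Aurkb (0.468, 0.392 to 0.558) and the spindle motor Kif11 (0.495, 0.447 to 0.548). The call of Kif11 was lost with TMM scaling. The proliferation marker Mki67 had 0.530 of the control level (0.506 to 0.555), short of 2-fold. Among 12 H3.3 and H3 chaperone genes, 3 fell and none rose (median -0.54, below all random lists). Those 3 were Chaf1b and Chaf1a, subunits of the replication-coupled factor CAF-1, at 0.309 and 0.419 of the control, and Asf1b at 0.475. Hira and Daxx, which handle H3.3, had log2 ratios of -0.64 and -0.38. Other members differed less, with Ubn1, Ubn2 and Cabin1 at -0.10, -0.20 and -0.20. Atrx, at 0.21, was the only 1 of the 12 above 0. Replication-dependent and linker histone genes, whose main transcripts lack a poly(A) tail and are poorly captured by oligo(dT), were tested for 5 of 34 members. Their median was 0.76 (percentile 98.5) with no member past the rule. Hist1h1c had a log2 ratio of 0.78 and Hist2h2be -0.12. Those were the only 2 members with a mean of at least 10 CPM, and as a mean of the 5 members the list had 0.66 and lay inside the random range.

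Fixed lists of progenitor regulators and of 3 signalling pathways also had lower medians. In the Hedgehog list 4 of 18 tested members fell and none rose (median -0.42, percentile 0.01). The 4 included all 3 Gli transcription factors, with Gli1 falling from 128 to 22 counts (0.181 of the control, 0.110 to 0.287), Gli2 to 0.445 (0.381 to 0.517) and Gli3 to 0.456 (0.406 to 0.513), and also Nkx6-2 (0.255, 0.0942 to 0.594). Ptch1, like Gli1 a target gene of the pathway, had nearly equal levels of 194 and 195 CPM (ratio 1.01, 0.941 to 1.08). The deposited table annotates 47 tested genes to smoothened (Hedgehog) signalling, a set looked at after the values were seen. Its median was -0.23, with 1 lower and none higher, and it holds none of the 3 Gli genes. In the Notch list 2 of 20 fell, Mfng (0.439, 0.385 to 0.498) and the ligand Dll4 (0.448, 0.221 to 0.860), and the median was -0.48, below all random lists. Dll4 lost its call with 5 counts added to each library. The wider set of 54 tested genes that the deposited table annotates to the Notch signalling pathway, looked at after the values were seen, had a median of 0.10, with 2 genes higher and none lower. Of the 20 genes in the fixed Notch list, 6 are also in the stem cell or the intermediate progenitor list. Of 17 tested Wnt targets, Sp5 (0.264, 0.128 to 0.504) and Sp8 (0.451, 0.388 to 0.522) fell, with a list median of -0.35 at percentile 0.385. The 109 tested genes annotated to the Wnt signalling pathway in that table had a median of -0.02, with 2 lower and none higher. The 35 genes annotated to the canonical Wnt signalling pathway had -0.18, with 1 lower and none higher. Neither set holds Sp5 or Sp8. BMP and TGF-beta targets had 7 log2 ratios above 0 and 7 below, with a median of -0.01 at percentile 52.7, and by the rule 2 of 14 rose and none fell. Without the filter on low counts that median was 0.45 and above the random range. Smad9 (2.18-fold, 1.16 to 4.24) and Ccn2 (2.18-fold, 1.14 to 4.35) rose there from 16 and 15 counts, and both calls were lost with 5 counts added. Stem cell and radial glia genes had a median of -0.28 (percentile 0.05), with 2 of 22 lower and 1 higher. The transcription factors Sox1 and Nr2e1 fell to 0.461 (0.427 to 0.497) and 0.476 (0.435 to 0.520) of the control, and Hopx rose 2.39-fold (1.36 to 4.34). Nes and Sox2 had 0.848 and 0.840 of the control level. Among intermediate progenitor and proneural genes 5 of 15 fell and none rose (median -0.73, below all random lists), among them Nhlh1 (0.214, 0.111 to 0.384), Eomes (0.318, 0.265 to 0.381) and Insm1 (0.419, 0.378 to 0.465).

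Neuronal genes were higher as a group, but not uniformly. In the neuron list 7 of 27 members rose and none fell, against a mean of 0.255 higher genes in matched random lists, and the median of 0.59 lay above all 10000 of them. Besides Slc17a7, these included the growth cone protein Gap43 (335 to 825 CPM, 2.46-fold, 2.36 to 2.57), the vesicle fusion protein Snap25 (2.45-fold, 2.24 to 2.67) and the neurofilament Nefl (2.59-fold, 2.20 to 3.05). Tubb3, a tubulin found throughout neurons, did not share this, at 1024 and 979 CPM (ratio 0.956, 0.928 to 0.985), and Syt1 had a log2 ratio of -0.77. The list of interneuron and GABA genes went both ways. Its median was -0.64, below all random lists, with 7 of 17 members lower and 1 higher. The lower members named by rule were transcription factors of the ventral forebrain, Dlx2 (2842 to 631 counts, 0.234, 0.215 to 0.256), Gsx2 (0.256, 0.195 to 0.332), Sp9 (0.308, 0.269 to 0.352) and Dlx5 (0.329, 0.275 to 0.392). The higher member was Sst, which encodes the neuropeptide somatostatin, with a log2 ratio of 1.02.

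**Figure D2:**
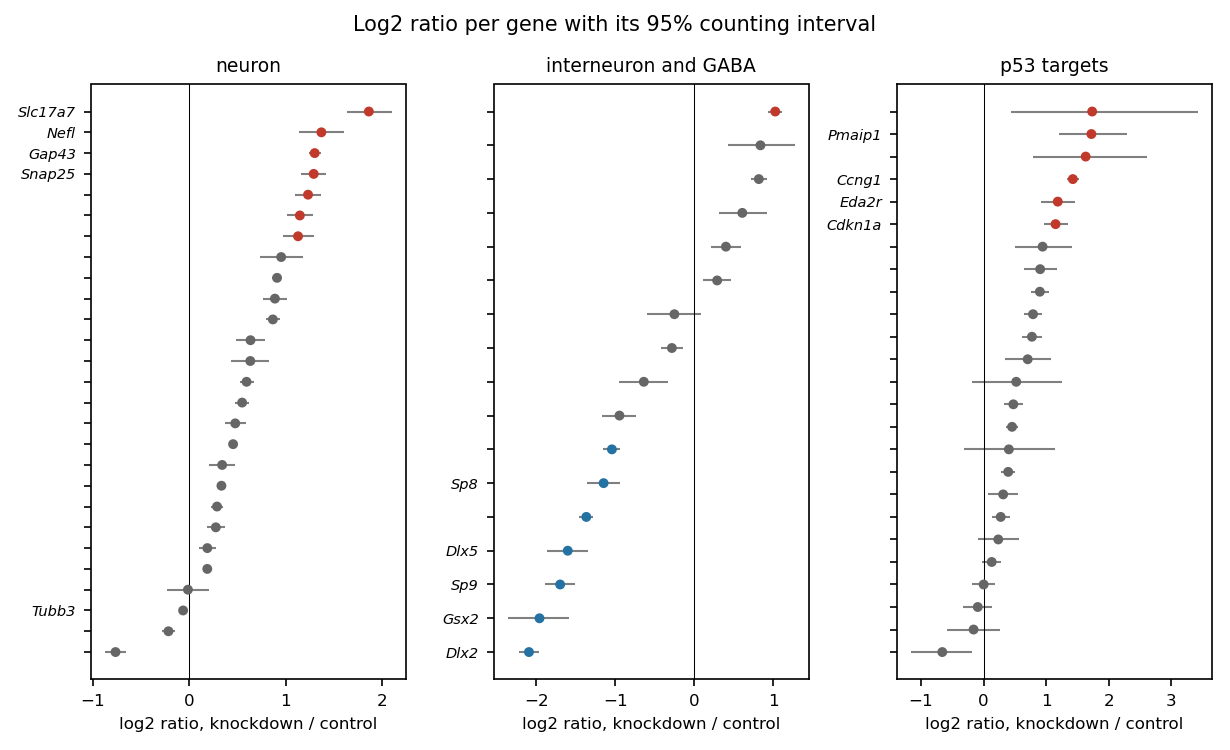
Log2 ratio of knockdown over control (horizontal axes) for each tested member of 3 fixed gene lists (rows, labelled for the genes named by rule), with horizontal lines for the 95% counting interval and 1 library per group. Red points are higher and blue points lower by the size rule, and grey points pass neither way. In the neuron list 7 of 27 members are red, from Slc17a7 at the top down, and in the p53 list 6 of 25.

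Oligodendrocyte genes fell most among the glial lists. Of 18 members 9 fell and 1 rose, and the median was -0.80, below all random lists. Besides Enpp6, the myelin regulator Myrf fell from 554 to 95 counts (0.181, 0.144 to 0.225) and Bcas1 from 2001 to 436 counts (0.230, 0.207 to 0.255). Mog was the member that rose, from 23 to 47 counts. Olig2, which is also expressed in progenitors, was at 391 and 409 CPM (ratio 1.05, 0.999 to 1.10). Astrocyte genes had a median of 0.00 (percentile 56.7), and S100b was the only 1 of 19 past the rule. Gfap, at 0.503 of the control (0.440 to 0.574), missed the threshold and passed it with DESeq2 size factors.

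Targets of the transcription factor p53 were higher as a group. Of 25 members 6 rose and none fell, and the median of 0.52 lay above all 10000 random lists. They included Ccng1 (129 to 346 CPM, 2.69-fold, 2.51 to 2.88), Pmaip1, which promotes apoptosis (3.33-fold, 2.30 to 4.90), Eda2r (2.28-fold, 1.89 to 2.76) and the cell cycle inhibitor Cdkn1a (2.22-fold, 1.94 to 2.54), whereas Mdm2, another p53 target, had a log2 ratio of 0.13. Apoptosis regulators had a median of 0.00 (percentile 67.1) and no member of 17 past the rule, with Mcl1 at 0.05 and Xiap at 0.10. Of 12 tested senescence-associated genes, Igfbp7 (4.61-fold, 2.36 to 9.83), Igfbp3 (2.38-fold, 2.01 to 2.82) and Cdkn1a rose and none fell. The list's median of 0.22 was at percentile 93.9, and it depended on the filter, at -0.40 with a minimum of 10 CPM and 0.32, above the random range, without a filter. The integrated stress response list had a median of 0.48, above all random lists, with 3 of 18 higher. These were Trib3 (8 to 35 counts, 4.62-fold, 2.10 to 11.5), the cystine transporter Slc7a11 (2.53-fold, 2.13 to 3.01) and Aldh1l2 (2.20-fold, 1.95 to 2.48). Slc7a11 lost its call after correction for gene length and GC content, at a log2 ratio of 0.95. The unfolded protein response list, by contrast, had a median of -0.02 (percentile 56.6) with none of 16 past the rule, and the chaperones Calr and Canx had log2 ratios of -0.12 and -0.02. Interferon response genes had a median of 0.21 at percentile 83.3, and 1 of 13, Gbp3, rose (8 to 21 counts, 2.77-fold, 1.18 to 7.23).

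Chromatin complexes other than the chaperones had few or no members past the rule. Kat8, the catalytic subunit of the MOF complexes that acetylate histone H4, had a ratio of 0.939 (0.782 to 1.13). The 12 genes of these complexes had a median of -0.26 at percentile 2.27, with none past the rule, and the median moved inside the random range when the mean was used (-0.20) or after the length and GC correction (-0.22). Hcfc1 and Ogt, the most abundant members, had 0.815 and 0.794 of the control level. Polycomb genes had a median of -0.13 at percentile 18.7, and none of 19 passed the rule (Rbbp4 0.815 and Rbbp7 0.865 of the control). None of the 29 Hox genes fixed as a list was analysed here. Of 20 germline genes 2 were tested, and Tdrd1 rose from 5 to 14 counts (2.96-fold, 1.01 to 10.5), a call lost with DESeq2 size factors. Imprinted genes had a median of 0.48, above all random lists, with 5 of 21 higher and 1 lower. Nnat, among the most abundant transcripts, rose from 2044 to 4175 CPM (2.04-fold, 2.01 to 2.08), and Rian (2.35-fold, 2.23 to 2.47), Zim1 (2.37-fold, 2.00 to 2.82) and Magel2 (2.06-fold, 1.60 to 2.65) also rose. H19 was the member that fell, with a log2 ratio of -1.13.

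The fixed lists of glycolysis and hypoxia and of cholesterol synthesis had lower medians. Glycolysis and hypoxia genes had a median of -0.38 at percentile 0.07, with Egln3 (0.442, 0.355 to 0.548) and the hexokinase Hk2 (0.478, 0.339 to 0.667) lower and Ndrg1 higher (2.12-fold, 1.75 to 2.58) among 18 tested. Hk2 lost its call with 5 counts added. Sets that the deposited table annotates were looked at after the values were seen and went apart. The 39 tested genes of the glycolytic process had a median of -0.16, with 1 higher and 1 lower. The 65 genes of the response to hypoxia had -0.06, with 3 higher and 1 lower. The 32 genes of the cellular response to hypoxia had 0.18, with 2 higher and none lower. Cholesterol synthesis genes had a median of -0.34 at percentile 0.09, with Fdps (65 to 28 counts, 0.455, 0.281 to 0.718) the only 1 of 19 that fell, a call lost after the length and GC correction. Of the annotated sets, the 21 genes of the cholesterol biosynthetic process had -0.28, with 2 lower and none higher. The 30 genes of the cholesterol metabolic process had -0.10, with 1 higher and 1 lower. Immediate early genes had a median of 0.03 (percentile 62.8). Dusp6 (90 to 286 counts, 3.35-fold, 2.64 to 4.30) and Ier3 (12 to 24 counts) rose and Fosl1 (26 to 12 counts) fell among 20 tested. Ier3 lost its call with 5 counts added and Fosl1 in 5 of the alternatives, TMM scaling among them.

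**Figure D3:**
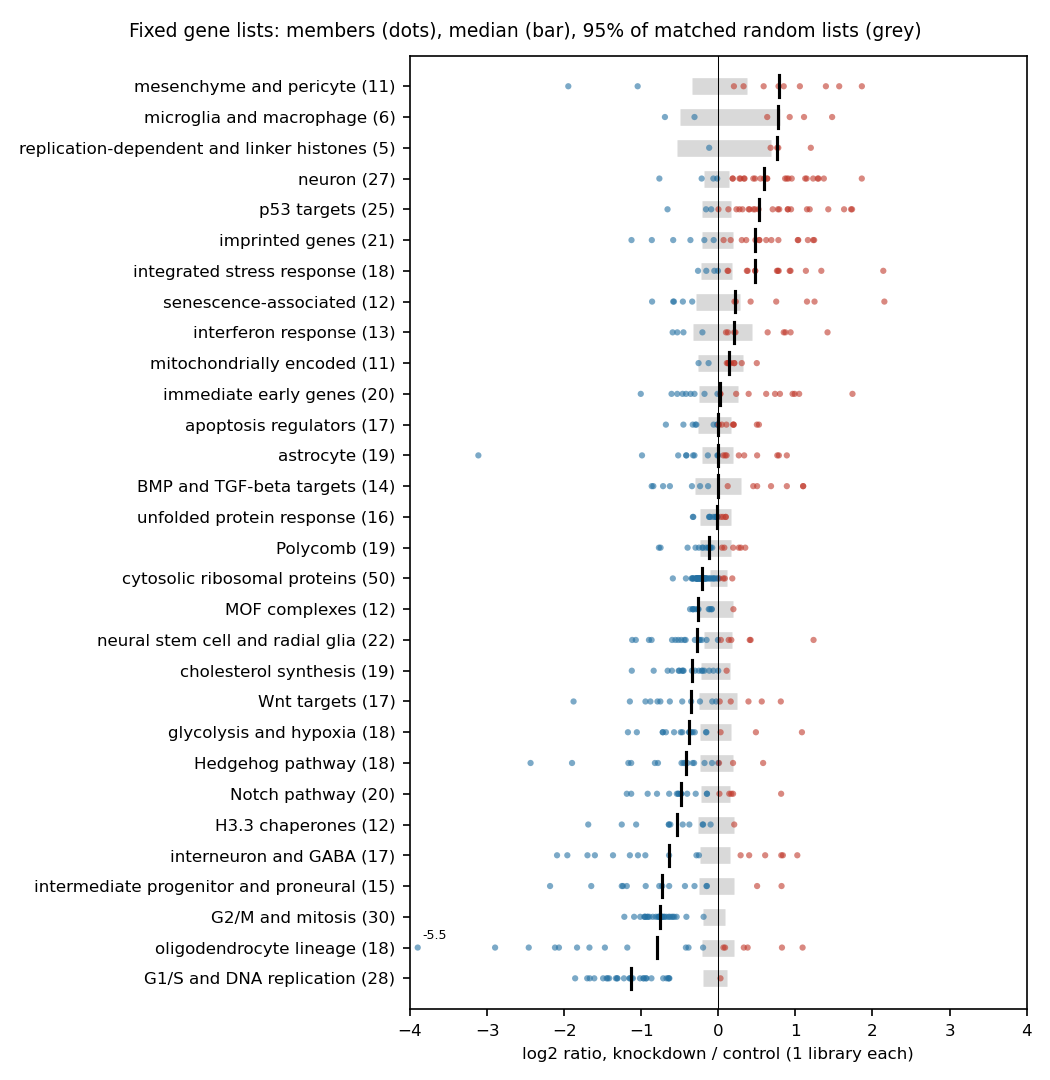
Log2 ratio of knockdown over control (horizontal axis) for the tested members (dots, red above 0 and blue below) of each fixed gene list with at least 5 tested genes (rows, number tested in brackets), 1 library per group. Black bars are list medians, from -1.14 for G1/S and DNA replication to 0.78 for mesenchyme and pericyte, grey bars span 95% of the medians of matched random lists, and Enpp6 at -5.50 is drawn at the left edge with its value.

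Among the lists of other cell types, only mesenchyme and pericyte genes lay outside their random range at the 1 CPM minimum. Mesenchyme and pericyte genes had a median of 0.78 (percentile 99.96) with 4 of 11 higher and 2 lower. The collagens Col3a1 (31 to 108 counts, 3.68-fold, 2.45 to 5.67) and Col1a2 (33 to 83 counts, 2.65-fold, 1.75 to 4.10) rose, whereas Pdgfrb (0.258, 0.186 to 0.351) and Prrx1 (0.483, 0.393 to 0.592) fell. With a minimum of 10 CPM, which left 5 members, the list median was 0.20 and inside the random range. Of 6 tested microglia and macrophage genes only C1qa rose, from 5 to 14 counts (2.96-fold, 1.01 to 10.5), a call lost with DESeq2 size factors, and the list median was 0.78 at percentile 97.3. Without the filter on low counts that median was 0.70 and above the random range. The 4 tested endothelial genes had a median of 0.39, also with Flt1 set at its bound, at percentile 74.5. No erythroid gene reached 1 CPM. As a measure of RNA makeup, mitochondrial transcripts took 3.27% of the control and 3.71% of the knockdown counts. The mitochondrially encoded list had a median of 0.14 at percentile 77.8, with mt-Co1 at 0.13 and mt-Cytb at 0.30. Cytosolic ribosomal protein genes had a median of -0.21 at percentile 0.02, and none of 50 passed the rule, with Rpl4 at 0.664 and Rplp0 at 0.889 of the control level.

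The authors' deposited table marks 1081 genes as significant, 664 up and 417 down, from a test on the same 2 libraries, which compares those libraries and not the conditions. Of these genes 879 also passed the size rule in the same direction (527 higher and 352 lower), and 11 genes passed the size rule without a mark in the authors' deposited table. Of all 1081 marked genes, 185 had a mean under 1 CPM. Counted separately, 35 of the 1081 had no count in the control, Flt1 among them. H3f3a and H3f3b are not marked in the authors' deposited table, where their log2 fold changes are -0.63 and -0.88. Gli1 is marked there, with a log2 fold change of -2.46.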

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

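The length and GC correction and the totals without mitochondrial genes were chosen after seeing the data. With 1 library per group no replicate could be left out, so nothing here measures the spread between cultures. No paired analysis was possible because each group holds 1 library. TMM factors, DESeq2 size factors and totals without the 20 most abundant genes shifted every log2 ratio by 0.02, -0.01 and 0.01, and left both H3.3 genes and every list with at least 5 tested members on the same side of the thresholds. The counts of higher and lower genes moved by over 1.5 times under 3 settings, by their construction. They were 169 and 174 with a minimum of 10 CPM, 1261 and 1147 at a fold threshold of 1.5, and 157 and 88 at a threshold of 3. Of 30 lists, 20 lay outside the random range, 6 above and 14 below, and 24 of the 30 kept their call under every alternative. A list inside the random range both times counted as kept, whatever the sign of its median. At 10 CPM the histone, microglia and interferon lists hold 2, 1 and 4 members, too few for a call there, but they were scored in this tally. The other 6 of the 30 lists changed, and the cause was not tested. Without the filter on low counts the medians were 0.45 for BMP and TGF-beta targets (reversed in sign), 0.70 for microglia and 0.32 for senescence genes, the 3 then above the random range. With a minimum of 10 CPM they were 0.33 for the 2 histones left, 0.20 for 5 mesenchyme genes and -0.40 for 8 senescence genes (reversed). As means of members they were 0.66 for replication-dependent histones and -0.20 for MOF complexes, and MOF complexes had -0.22 after the length and GC correction. Among 107 named genes, 806 of 822 alternative values kept the call, 15 lost it, 1 gained it (Gfap) and none reversed. These values came from the scaling, filter and added-count alternatives, the length and GC correction and the totals without mitochondrial genes. Named genes were not followed at other fold thresholds, without the interval or with the authors' deposited log2 fold changes. Of the 85 named genes past the size rule, 74 passed it under every alternative so followed that gave a value.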

Other observations

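All gene groups and tests in this part were chosen after the results were seen, except the fixed lists named as such. Of 600 biological process terms with 15 to 200 tested genes, carried by the deposited table, the terms farthest from their matched random lists, in SDs of those lists, were DNA replication initiation on the lower side (median log2 ratio -1.11, 10 of 15 genes lower) and synaptic transmission on the higher side (median 0.46, 11 of 81 genes higher and 2 lower). Terms of ion channels and inhibitory receptors were also high. Potassium ion transmembrane transport had 13 of 57 genes higher and none lower (median 0.39), with Kcnmb2, Kcna1 and Kcnh3 rising 4.16-fold, 3.43-fold and 3.05-fold. The gamma-aminobutyric acid signalling term had a median of 0.61 over 17 genes, with the receptor subunits Gabrq and Gabra3 rising 3.50-fold and 2.15-fold. The chloride transporter Slc12a5, which sets the response to GABA in maturing neurons, rose from 763 to 1987 counts (2.75-fold, 2.53 to 2.99), and the calcium channel Cacna1g from 304 to 951 counts (log2 ratio 1.72). RNA splicing (median -0.21, 181 genes, 3 lower) and translation (median -0.18, 160 genes) had medians slightly below 0.

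Of 14 targets and feedback inhibitors of FGF and ERK signalling, 4 rose and 10 did not pass the rule. The list was prompted by Etv4, Dusp5 and Dusp6, and the other 11 genes had a median log2 ratio of 0.61 at percentile 99.98 of matched random lists, with 9 above 0. Among these, Etv5 rose from 346 to 1060 counts (3.23-fold, 2.86 to 3.66), and Spry4, Spry2 and Spry1 had log2 ratios of 0.99, 0.80 and 0.75 without passing the rule, while Etv1 had -0.37 and Dusp4 -0.01. Annotated terms of these pathways, which hold none of the 4 genes that rose, lay nearer to their matched random lists. The fibroblast growth factor receptor signalling term had a median of 0.08 over 19 genes (0.97 SDs above), with 5 higher and none lower. The MAPK cascade term had 0.09 over 37 genes (1.27 SDs above), with 1 higher and 2 lower. Within the fixed interneuron and GABA list, transcription factors went both ways, since Lhx6 and Lhx8 had log2 ratios of 0.29 and 0.84 beside lower ones such as Dlx1, Dlx2, Dlx5, Gsx2, Sp8 and Sp9. The genes of GABA synthesis and neuropeptides also differed, with Gad1 at 0.82, Npy at 0.61 and Gad2 at -0.28. Choroid plexus and epithelial genes did not move together. Ttr and Epcam rose from 4 and 2 counts to 38 and 25, whereas Cdh1 fell from 24 to 10 and Otx2 had a log2 ratio of -0.63. Sex-linked transcripts, a measure of the mix of embryos, differed little, with log2 ratios of -0.06 for Xist, -0.04 for Kdm5d and 0.28 for Ddx3y. Among mitochondrial genes, mt-Co2 held 14 and 11 counts and mt-Atp6 29 and 39, far below mt-Atp8 with 13805 and 14294.

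Lower replication genes and higher neuronal genes formed the first pattern. Gene length or GC bias as the whole cause is argued against, since the medians after subtracting those trends were -1.11 and 0.53, both still outside the random range. Scaling set by a few abundant genes is argued against too, because leaving out the 20 most abundant genes shifted every ratio by 0.0115, and 1 factor cannot lower one list and raise the other. A candidate explanation that stays open and was not tested is a lower share of dividing progenitors with a larger share of neurons, or more mature neurons, and the H3.3 knockdown itself, off-target effects of its construct and a difference between the 2 cultures are confounded with 1 library per group.

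Lower oligodendrocyte genes formed the second pattern. The median of the fixed list after the length and GC correction was -0.78, still below the random range, which argues against that bias as the whole cause. Members known from progenitors on went apart, with Sox10 (1444 to 493 counts) and Nkx2-2 (314 to 93 counts) falling, and Pdgfra and Cspg4 at log2 ratios of -0.20 and 0.33. Myelin genes went apart too, with Mag and Mbp falling, Cnp at -0.39 and Mog rising. The wider set of 30 tested genes annotated to myelination in the deposited table did not share the fall. Its median was 0.04, with 1 gene higher and 2 lower. A smaller share of the lineage, a block or delay within it and lower transcription in its cells all may remain as explanations, and none of them was tested.

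The H3.3 genes themselves formed the third pattern, since their transcripts were still at 0.646 and 0.544 of the control. The only H3.3 copy listed under an H3f3 symbol, H3f3c, had 3 counts in all against 3099 at H3f3a. Copies under other names were not searched for, and how reads shared between copies were counted is not given in the sources used here, so the part of copies stays open. A fall shared with other polyadenylated histone genes cannot be told apart from the knockdown. The 8 other such genes had a median of -0.57, with H2afz at -0.81 and H2afx at -0.65, so H3f3a at -0.63 lies inside their range and H3f3b at -0.88 just below it. What keeps this open is that histone variant genes and cell division may have moved together in these libraries, and cells without the virus could also leave H3.3 transcripts.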
